A study of Mus musculus with 10 samples.

How the data were processed

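RNA from 10 MB-49 tumors was sequenced in bulk, 5 from mice given the GARP antibody PIIO-1 and 5 from mice given PBS. Each mouse received 100000 MB-49 cells. Per the labels' protocols and the series' design text, tumors were made into single-cell suspensions, total RNA was isolated with RNeasy kits, and libraries were made with an NEBNext Ultra RNA kit. Groups were taken from the treatment label, and replicate numbers from the sample titles, whose column names carry another name for the antibody, a4D3. HISAT2, featureCounts and DESeq2 are named with build GRCm38 in the submitters' processing notes; their versions, the annotation and the strand setting are not given in the sources used here.

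The deposited values are normalized counts, a signal that is never negative, with 1 column per tumor and 24202 gene symbols; per the submitters' processing notes and the name of the table they are gene counts scaled by DESeq2. Each deposited column was divided by its smallest step (between 0.817 and 1.56 normalized counts per read) to recover whole reads, and 100% of the values came out whole within 0.001 read. Median-ratio size factors recomputed from those reads differed from the deposited ones by a ratio between 0.99994 and 1.00008. The recovered totals ranged from 18843192 to 37581521 reads per tumor, so 3 reads are worth between 2.45 and 4.68 normalized counts. No pair of libraries was alike within counting noise (smallest chi-square per gene 9.80). Because the strand setting is not given, a gene and an overlapping or antisense partner cannot be told apart; among the genes named this concerns Foxp3, Ifng, Cxcl10, Cd274, Dubr, Amigo2, Def8, Tnfsf13b, C1s1, Mrps34, Thbs1, Smurf2, Fn1, Pi16, Cd244a, Ccl2, Vcam1, Igtp, Erap1, Tapbp, H2-Oa, Zbtb46, Itga2b, Eng, Cdh5, Ttn, Mbp, Hk2, Uqcrc2 and Gm17828. Genes with near-identical copies (globins, Ifi200 family, Gbp, H2-Q, Klra, Hspa1a and Hspa1b) are uncertain where counting could split their reads. Coordinates come from the GENCODE annotation of GRCm38, in which 23960 of the 24202 symbols (99.0%) matched 1 gene.

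Values were analysed as log2(value + 1) for the 16767 genes with a mean of at least 10 normalized counts; such differences understate the change of low genes. The main test was limma 3.58.1 in R 4.3.3 with an intensity trend, PIIO-1 against PBS over all 10 tumors, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fixed lists of at least 5 measured genes were tested by camera with a preset inter-gene correlation of 0.01, and members were also adjusted over the list alone. A list score per tumor (mean log2 value) was compared by an exact two-sided permutation test over 252 regroupings, and the SE printed beside a list's mean is that of this score's difference between the groups. The 32 lists were the GARP and latent TGF-beta axis, TGF-beta response, extracellular matrix, fibroblasts, T cells, CD8 and cytotoxic effectors, exhaustion and checkpoints, regulatory T cells, T cell trafficking, interferon-gamma response, type I interferon response, MHC class I, MHC class II, NK cells, B and plasma cells, dendritic cells, macrophages, monocytes and neutrophils, mast cells, platelets, endothelium, epithelium, keratinocytes, skeletal muscle, adipocytes, red blood cells, nerve, cell cycle, hypoxia and glycolysis, epithelial-mesenchymal transition, dissociation and immediate early stress, and oxidative phosphorylation. Some genes stand in more than 1 list (Cdh1, Fn1, Ifng, Cxcl9 and Hdc among them). Groups, lists, tests and alternatives were fixed before the data were examined, except those named below as chosen later.

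Genes named in the text follow a rule fixed at the same time: a panel of 12 genes (Lrrc32, Tgfb1, Cd8a, Cd4, Foxp3, Gzmb, Ifng, Cxcl9, Cxcl10, Cxcr3, Pdcd1 and Cd274), the 8 genes with the smallest p in each direction where fewer passed, with a mean of at least 50 normalized counts in the higher group and without unnamed gene models, and the 2 members of each list with the smallest p. Some genes that this rule names are not reported here. Other genes named were chosen after their values were seen.

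Alternatives were a pseudocount of 0.5 or 5, no filter, a minimum mean of 50, TMM or upper-quartile scaling, limma without a trend or with array weights, the replicate number as a block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald) on the recovered whole reads of the same genes, a 2-fold minimum, camera with an estimated correlation, fry, a median score, and each tumor left out in turn. Chosen after the data were seen were PIIO-1 tumor 5 and PBS tumor 4 left out together, the level of Ptprc (CD45) as a covariate, and DESeq2 with each tumor left out. DESeq2 was run first with no filter and then, after that count had been seen, on the same genes as limma; both counts are given. On simulated data for PIIO-1 against PBS with 16767 genes, 200 genes were changed, and all genes were drawn independently of each other. A further short list of genes was shifted together, and its calls were not counted as false. The limma step recovered 55.2% of genes changed 1.5-fold, 73.6% of those changed 2-fold, 88.4% at 3-fold and 94.8% at 4-fold. Of its calls, 4.29% were false. Correlated genes and other numbers of changed genes were not simulated. No read-level data were analysed here.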

Results

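MB-49 tumors were grown from a mouse bladder cancer cell line placed under the skin of the right flank. The mice carried a knocked-in human LRRC32 gene. Tumors were made into single-cell suspensions before bulk RNA sequencing. LRRC32 encodes GARP, the cell-surface protein that holds latent TGF-beta, and PIIO-1 is the GARP antibody named in the treatment label. PIIO-1 was given at 200 ug per mouse into the peritoneum on days 6 and 9, and 5 PIIO-1 tumors were compared with 5 tumors of PBS-treated mice, all collected on day 10. The libraries held between 18843192 (PBS tumor 4) and 37581521 (PBS tumor 3) whole reads in genes, and PIIO-1 libraries between 29689555 and 35299028. The labels do not say that the tumors came from separate animals, so every p-value measures the spread between these samples. Levels are normalized read counts given as mean ± SD of 5 tumors per group, and differences are on the log2(normalized count + 1) scale, PIIO-1 minus PBS, with the standard error (SE) from limma.

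The design asks how the GARP antibody shifts the transcripts of the tumor. Ifi208, an interferon-inducible gene of the Ifi200 family at chromosome 1, 173673675 to 173698395 (plus strand, GRCm38), stood at 506 ± 202 normalized counts in PBS and 195 ± 40.3 in PIIO-1 tumors, a difference of -1.30 (SE 0.25). Its highest PIIO-1 value (247) lay below its lowest PBS value (300.4). Trib1, a pseudokinase that guides degradation of C/EBP transcription factors, stood at 7372 ± 584 in PBS and 9455 ± 815 in PIIO-1 tumors, a difference of 0.36 (SE 0.070). Gm17828, a processed pseudogene inside Zfp280d at chromosome 9, 72292542 to 72293340, which was singled out after its values were seen, stood at 123 ± 15.5 and 57.4 ± 19.7. DESeq2 on the recovered whole reads called these 3 genes, with adjusted p of 0.00110 for Ifi208, 0.0307 for Trib1 and 0.0183 for Gm17828. limma, the main test, called 0 of 16767 genes, and edgeR called 0. The smallest adjusted p by limma was 0.837, which all 3 genes share.

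At an unadjusted p under 0.05, limma counted 944 genes (480 higher and 464 lower in PIIO-1 tumors) where chance gives 838 on average, edgeR counted 975 and DESeq2 1012. Other groupings of the 10 tumors gave limma a median of 613 such genes, and 26 of 100 groupings, the real one included, gave at least 944. The 2 groups did not overlap for 66 genes with higher and 77 genes with lower values in PIIO-1 tumors, where chance gives 133 genes. The higher genes with the smallest p after Trib1 were Ccl9 (a CC chemokine, difference 0.73, SE 0.16), Dubr (0.21, SE 0.047), Mrpl52 (0.19, SE 0.042), Gfod1 (0.27, SE 0.061), Insig1 (a brake on sterol synthesis, 0.39, SE 0.088), Dbi (0.23, SE 0.054) and Sgk1 (a glucocorticoid-regulated kinase, 0.25, SE 0.061). The lower genes after Ifi208 were Amigo2 (-0.33, SE 0.071), Slc25a40 (-0.22, SE 0.051), Suox (-0.27, SE 0.064), Def8 (-0.24, SE 0.057), Tnfsf13b (the B cell survival factor BAFF, -0.27, SE 0.064), C1s1 (a complement protease, -0.31, SE 0.077) and Mrps34 (-0.25, SE 0.063). None of these 14 genes passed any of the 3 tests over all genes. With 1 tumor left out in turn, Ifi208 passed in 9 of 10 DESeq2 fits (adjusted p up to 0.0489) and Gm17828 in 5 of 10, neither with an adjusted p without PIIO-1 tumor 4, while Trib1 passed in 4 of 10. DESeq2 was run first on all genes with a read and no filter, where it called 2 genes, Ifi208 and Gm17828; the fit on the kept genes, which added Trib1, was run after that count had been seen.

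**Figure D1:**
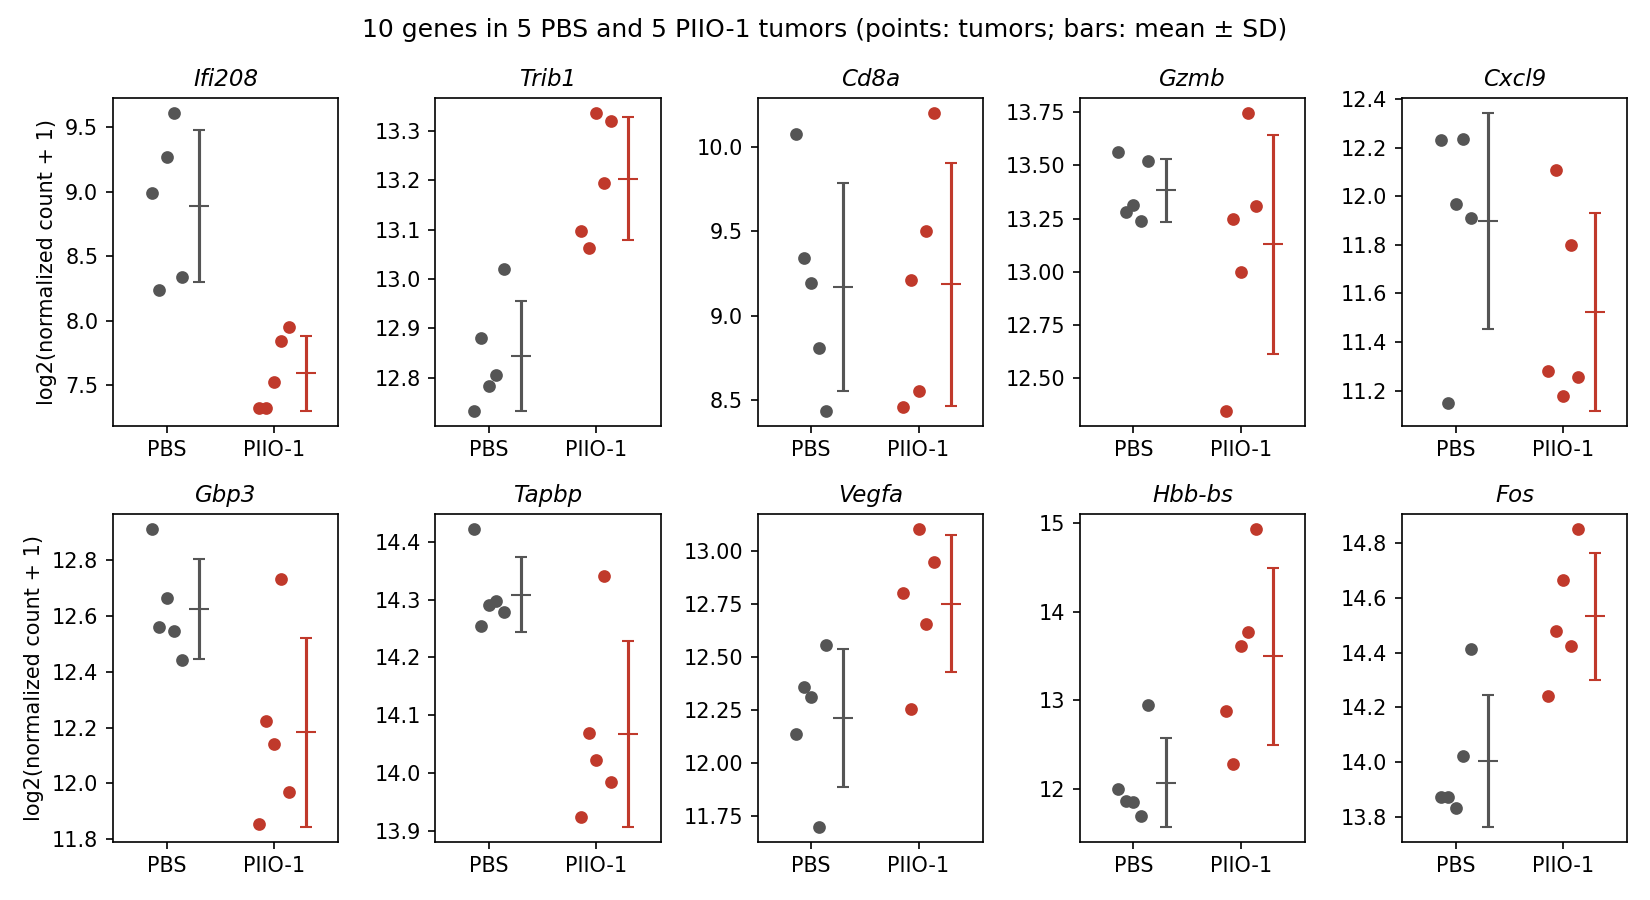
Levels of 10 genes, as log2(normalized count + 1) on the vertical axes, in 5 PBS (grey) and 5 PIIO-1 (red) tumors; each point is a tumor and the bars are the mean ± SD of the group. Ifi208 and Trib1 separate the groups without overlap, while Cd8a ranges from 345 to 1077 normalized counts in PBS and from 351 to 1175 in PIIO-1 tumors.

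Genes of the antibody's target axis gave no call. Lrrc32 stood at 94.0 ± 27.1 in PBS and 95.8 ± 17.8 in PIIO-1 tumors, a difference of 0.054 (SE 0.20); reads of the knocked-in human sequence count there only as far as they align to the mouse gene. Tgfb1 stood at 5409 ± 740.2 and 6015 ± 777, a difference of 0.15 (SE 0.11). Of 20 measured members of the GARP and latent TGF-beta list 0 passed, and the list's mean difference was 0.052 (SE 0.036). Thbs1, an activator of latent TGF-beta, differed by 0.49 (SE 0.23; 0.27 without PIIO-1 tumor 5) and the integrin gene Itgb6 by -0.44 (SE 0.21; -0.27 without PIIO-1 tumor 2). The TGF-beta response genes were higher as a set by camera, with a mean difference of 0.13 (SE 0.11) and 16 of 20 members positive. Its adjusted p = 0.00431 became adjusted p = 0.705 with an estimated correlation. Smurf2, a ubiquitin ligase that limits TGF-beta signalling, differed by 0.13 (SE 0.044). Over all genes or adjusted over the list alone, 0 of the 20 members passed. The mean was 0.070 without PIIO-1 tumor 5, 0.082 without PBS tumor 4 and 0.19 without PIIO-1 tumor 2. This set had a mean of 0.026 and an adjusted p of 0.110 without PIIO-1 tumor 5 and PBS tumor 4, the tumors farthest out on the first 2 principal components, which were left out together after the data were seen.

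T cell and cytotoxic genes showed no difference that passed a test. Cd8a stood at 620.1 ± 281 in PBS and 643 ± 335 in PIIO-1 tumors, a difference of 0.014 (SE 0.35, 95% interval -0.76 to 0.79), so a 1.5-fold change either way lies inside its interval. Cd4 differed by -0.098 (SE 0.26) and Foxp3 by -0.041 (SE 0.24). The checkpoint receptor gene Pdcd1 differed by 0.00099 (SE 0.34), its ligand gene Cd274 by -0.012 (SE 0.25) and the chemokine receptor gene Cxcr3 by 0.15 (SE 0.32). The effector genes Gzmb (granzyme B), Prf1 (perforin) and Ifng differed by -0.25 (SE 0.20), -0.27 (SE 0.18) and -0.40 (SE 0.28), with -0.059 for Gzmb and -0.11 for Prf1 without PIIO-1 tumor 1 and -0.19 for Ifng without PBS tumor 1. Of 21 T cell genes 0 passed (mean -0.030, SE 0.30; Trbc1 -0.24, SE 0.23; Il7r 0.25, SE 0.25). Of 23 CD8 and cytotoxic genes 0 passed (mean -0.051, SE 0.23). The 16 exhaustion and checkpoint genes had a mean of 0.12 (SE 0.20), with Cd244a at 0.35 (SE 0.16) and Havcr2, which encodes TIM-3, at 0.24 (SE 0.12). The 13 regulatory T cell genes had a mean of 0.076 (SE 0.19), with the IL-33 receptor gene Il1rl1 at 0.70 (SE 0.27) and Izumo1r at -0.34 (SE 0.19). The 20 trafficking genes had a mean of 0.088 (SE 0.21), with Ccl2 at 0.37 (SE 0.16) and Vcam1 at -0.34 (SE 0.16). The 15 NK cell genes had a mean of -0.066 (SE 0.23; median -0.12), with Klra1 at -0.30 (SE 0.29) and Cma1, a chymase gene of mast cells that raises this mean, at 0.80 (SE 0.42; 0.37 without PIIO-1 tumor 5). The signs of 5 of these 6 list means rest on single tumors. The T cell, CD8 and NK cell means were positive (0.011 to 0.14) without PBS tumor 1 or PIIO-1 tumor 1 or 3, and the regulatory T cell and trafficking means negative (-0.0162 to -0.00540) without PIIO-1 tumor 4 or 5. The exhaustion mean kept its sign but ran from 0.0049 without PIIO-1 tumor 5 to 0.24 without PIIO-1 tumor 1. Camera called none of these 6 lists, and 0 of their members passed over all genes or adjusted over the list alone.

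Interferon-gamma response and antigen presentation genes were lower as sets in PIIO-1 tumors by camera with a preset correlation (adjusted p of 7.96e-06 for interferon-gamma response, 1.78e-07 for MHC class I and 0.0319 for MHC class II), but none of these 3 sets was called with an estimated correlation (adjusted p = 0.713, 0.705 and 0.829). Of 26 interferon-gamma response genes 24 were negative, with a mean difference of -0.24 (SE 0.18). The mean was -0.13 without PIIO-1 tumor 1 and -0.39 without PIIO-1 tumor 4, which have the lowest (11.42) and the highest (12.46) score of the 10 tumors. Gbp3, an interferon-induced GTPase, differed by -0.44 (SE 0.15), the related Igtp by -0.37 (SE 0.13), and the T cell chemokine genes Cxcl9 and Cxcl10 by -0.37 (SE 0.23) and -0.14 (SE 0.19). All 18 measured MHC class I presentation genes were negative, with a mean of -0.17 (SE 0.10). Members of a list can move together (estimated correlation 0.794 here), so counts of signs in this and the other lists are not counts of independent genes. The exact permutation p of the list score was 0.135 for MHC class I and 0.246 for interferon-gamma response. Tapbp (tapasin) stood at 20306 ± 944 in PBS and 17259.9 ± 2037 in PIIO-1 tumors (difference -0.24, SE 0.075). Erap1, which trims peptides for MHC class I, differed by -0.20 (SE 0.057). Of 11 MHC class II genes 10 were negative, with a mean of -0.21 (SE 0.27), H2-DMb1 at -0.32 (SE 0.18) and H2-Oa at -0.39 (SE 0.26). Of the 22 type I interferon response genes 19 were negative, with a mean of -0.094 (SE 0.16), Xaf1 at -0.22 (SE 0.11) and Ifi44 at -0.31 (SE 0.21). Their mean was -0.020 without PIIO-1 tumor 1 and -0.21 without PIIO-1 tumor 4. This list was not called (camera, adjusted p = 0.0842). In these 4 lists 0 members passed over all genes or adjusted over the list alone. The MHC class II call was lost without PBS tumor 1, 4 or 5 or PIIO-1 tumor 1 or 3 (adjusted p between 0.0783 and 0.411). Its mean was -0.11 without PBS tumor 1, -0.10 without PIIO-1 tumor 1 and -0.056 without PIIO-1 tumor 3, but -0.36 without PBS tumor 2 and -0.33 without PIIO-1 tumor 4.

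Camera with a preset correlation called the neutrophil, dendritic cell, B cell and mast cell sets higher in PIIO-1 tumors (adjusted p of 0.000140, 0.0133, 0.0161 and 0.0167), but not the macrophage set. With an estimated correlation it called none of them (adjusted p = 0.705, 0.764, 0.713 and 0.705). All 16 monocyte and neutrophil genes were positive, with a mean difference of 0.37 (SE 0.26). Mmp8, a neutrophil collagenase, differed by 0.48 (SE 0.20) and Retnlg by 0.75 (SE 0.36). Of 15 dendritic cell genes 13 were positive, with a mean of 0.25 (SE 0.25), Zbtb46 at 0.47 (SE 0.24) and the migration receptor gene Ccr7 at 0.47 (SE 0.25). Of 12 B and plasma cell genes 10 were positive, with a mean of 0.48 (SE 0.36), Cd79a at 0.79 (SE 0.37) and Ighd at 0.76 (SE 0.39). All 6 mast cell genes were positive, with a mean of 0.67 (SE 0.44). The IgE receptor genes Ms4a2 and Fcer1a differed by 1.28 (SE 0.53) and 0.80 (SE 0.41). In these 4 sets 0 members passed over all genes or adjusted over the list alone. The 16 macrophage genes had a mean of 0.14 (SE 0.23), with Chil3 at 1.03 (SE 0.43) and the complement gene C1qa at -0.34 (SE 0.21), and were not called. Their mean ran from 0.040 without PBS tumor 1 to 0.30 without PBS tumor 5. PIIO-1 tumor 5 had the highest B cell, mast cell and neutrophil scores of the 10 tumors. It also held the highest Cd79a (142.5 normalized counts), Ighd (105.3) and Fcer1a (124.3), against at most 79.4, 42.3 and 56.1 elsewhere. Without it the means of the B cell, mast cell, dendritic cell and neutrophil sets were 0.19, 0.30, 0.15 and 0.19, with adjusted p of 0.260, 0.169, 0.0961 and 0.0294. The B cell, mast cell and dendritic cell calls were also lost without PIIO-1 tumor 4. The mast cell call was lost without PBS tumor 4 and the dendritic cell call without PBS tumor 2, with adjusted p between 0.0550 and 0.375 over all fits that lost a call. The dendritic cell mean was 0.090 without PBS tumor 2 and 0.16 without PIIO-1 tumor 4. Without PIIO-1 tumor 5 and PBS tumor 4 together the neutrophil set had a mean of 0.10 and an adjusted p of 0.297. PIIO-1 tumors 4 and 5 also had the highest red blood cell scores (10.3 and 11.4) and platelet scores (8.32 and 8.53). Whether blood content carries these immune sets was not tested.

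Red blood cell transcripts differed most among the lists. All 6 measured members were positive, with a mean difference of 1.22 (SE 0.45). The beta-globin gene Hbb-bs stood at 4546 ± 1886 in PBS and 14045 ± 10244 in PIIO-1 tumors (difference 1.42, SE 0.42). The alpha-globin gene Hba-a2 stood at 250 ± 108 and 805 ± 479 (difference 1.56, SE 0.39). Globin genes held 0.0246% ± 0.00937 of the reads in PBS and 0.0765% ± 0.0608 in PIIO-1 tumors (SD, n = 5; exact permutation p = 0.0238), with the highest share, 0.180%, in PIIO-1 tumor 5. All 6 platelet genes were positive, with a mean of 0.40 (SE 0.15), Ppbp at 1.31 (SE 0.40) and Itga2b, the platelet integrin, at 0.42 (SE 0.12). Of the others, Pf4 differed by 0.51 (SE 0.25). Itgb3 (0.11, SE 0.22), Gp1ba (0.035, SE 0.21) and Clec1b (0.013, SE 0.32) lay within their SE of 0. Over all genes 0 members passed, while 5 red blood cell and 2 platelet genes passed adjusted over the list alone. Camera gave adjusted p of 1.40e-05 and 0.0167, and adjusted p = 0.488 for both with an estimated correlation. Without PIIO-1 tumor 5 the red blood cell mean was 0.87, and the platelet call was lost without PBS tumor 4 or PIIO-1 tumor 4 (adjusted p of 0.0594 and 0.0632). Near-identical globin copies (Hba-a1 with Hba-a2, Hbb-bs with Hbb-bt) may share reads, so their single values are uncertain.

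Immediate early and stress genes and hypoxia genes were also higher as sets by camera with a preset correlation (adjusted p of 8.03e-09 and 4.41e-06), but not called with an estimated correlation (adjusted p = 0.488 and 0.705). Fos and Fosb, which encode AP-1 subunits induced within minutes of a stimulus, differed by 0.53 (SE 0.13) and 0.87 (SE 0.21). In all, 17 of 18 members of the stress list were positive, with a mean of 0.46 (SE 0.18). Of 20 hypoxia and glycolysis genes 19 were positive, with a mean of 0.23 (SE 0.16), which was 0.13 without PIIO-1 tumor 3 and 0.15 without PBS tumor 4. Vegfa, the angiogenic factor, stood at 4837 ± 1009 in PBS and 7040 ± 1490.0 in PIIO-1 tumors (difference 0.54, SE 0.17). Hexokinase 2 (Hk2) differed by 0.35 (SE 0.11). Over all genes 0 members passed; adjusted over the list alone, 3 stress genes (Fosb, Fos and Jun) and 0 hypoxia genes passed. PIIO-1 tumor 5 also held the largest share of mitochondrial reads, 3.12% against 0.986% to 2.22% in the other tumors. Without it the stress mean was 0.33.

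Of the tumor cell, stromal and neighbouring tissue lists, camera with a preset correlation called the epithelial-mesenchymal transition set alone (adjusted p = 0.0243, and adjusted p = 0.488 with an estimated correlation). It had a mean of 0.16 (SE 0.052) with 11 of 14 members positive. Its members with the smallest p were Cdh1, the epithelial cadherin that the transition lowers, at 0.72 (SE 0.31), and the matrix gene Fn1 at 0.63 (SE 0.32). Members are scored without direction, so the rise of Cdh1 counts toward the call. The call was lost without PBS tumor 1 or PIIO-1 tumor 1 or 5 (adjusted p between 0.0831 and 0.109). Extracellular matrix genes had a mean of 0.023 (SE 0.25; median -0.038), with Col6a2 at 0.23 (SE 0.16). Fibroblast genes had a mean of 0.039 (SE 0.22), with Pi16 at 0.42 (SE 0.23) and Pdpn at 0.13 (SE 0.081). Endothelial genes had a mean of 0.041 (SE 0.24), with Eng at -0.17 (SE 0.079) and Cdh5 at 0.12 (SE 0.11). Epithelial and urothelial genes had a mean of 0.053 (SE 0.099), with Epcam at -0.45 (SE 0.26). Cell cycle genes had a mean of -0.021 (SE 0.053), with Cenpa at 0.11 (SE 0.056) and Mcm5 at -0.10 (SE 0.059). Oxidative phosphorylation genes had a mean of 0.0040 (SE 0.031) against a median of -0.0087 and a camera direction that was also downward, with Ndufa4 at 0.15 (SE 0.060) and Uqcrc2 at -0.084 (SE 0.042). With 1 tumor left out, the means of these 6 uncalled lists turned sign, down to -0.148 for matrix and -0.136 for fibroblast genes without PIIO-1 tumor 1, -0.0878 for endothelial genes without PBS tumor 2, -0.0311 for epithelial genes without PBS tumor 4 and -0.0131 for oxidative phosphorylation genes without PBS tumor 4, and up to 0.00613 for cell cycle genes without PIIO-1 tumor 4. Keratinocyte genes had a mean of 0.29 (SE 0.47; 0.037 without PBS tumor 4), and Krtdap (1.18, SE 0.32) passed adjusted over the list alone while Krt14 (0.41, SE 0.16) did not. Skeletal muscle genes had a mean of 0.19 (SE 0.18; 0.034 without PIIO-1 tumor 5), with Ttn at 0.49 (SE 0.15) and Eno3 at -0.11 (SE 0.077). Nerve and Schwann cell genes had a mean of -0.095 (SE 0.063), with Mbp at 0.075 (SE 0.058). Adipocyte genes had a mean of 0.15 (SE 0.18; -0.017 without PIIO-1 tumor 5) and a camera direction that was downward, with Pnpla2 at -0.13 (SE 0.059) and Lpl at -0.44 (SE 0.30). Apart from the epithelial-mesenchymal transition set, camera called none of these 10 lists, and apart from Krtdap 0 of their members passed adjusted over the list alone.

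**Figure D2:**
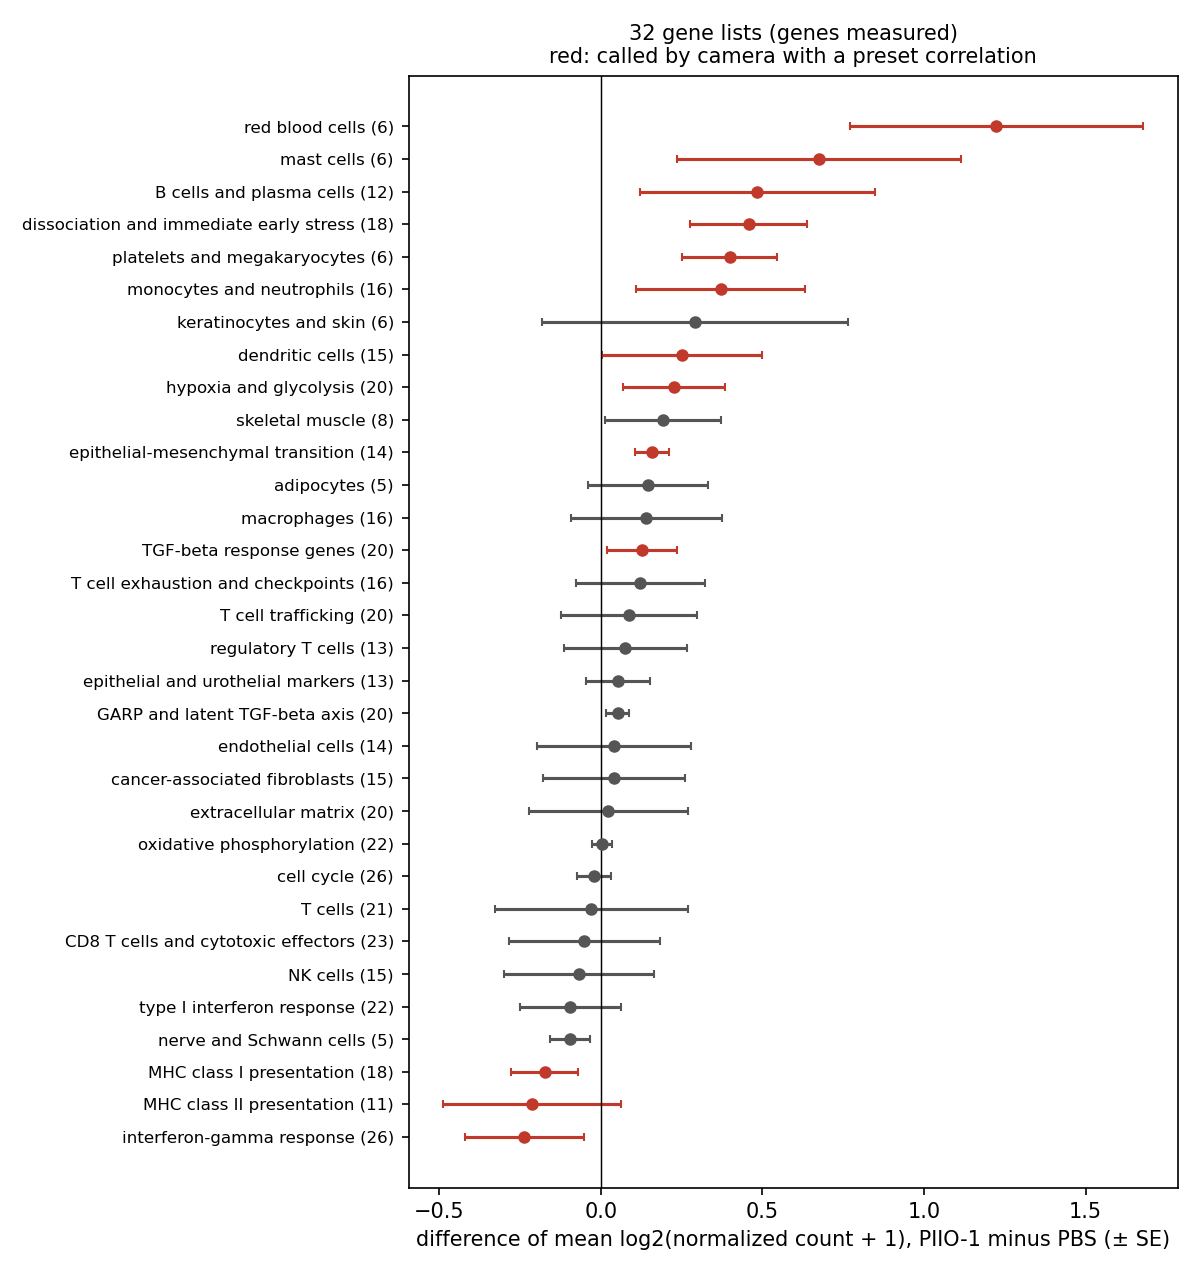
Difference of the mean log2(normalized count + 1) between 5 PIIO-1 and 5 PBS tumors for 32 gene lists, with the SE of the difference; the number of measured genes stands in parentheses and red marks the 13 lists that camera called with a preset correlation. Red blood cell genes lie farthest up (1.22) and interferon-gamma response genes farthest down (-0.24).

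Over the 32 lists, camera with a preset correlation called 13 (10 higher and 3 lower in PIIO-1 tumors). Camera with a correlation estimated for each list called 0, and fry, which asks whether a set's genes move one way on balance, called 0 (smallest adjusted p = 0.366). The score of each list per tumor, compared by an exact two-sided permutation test whose smallest possible p is 0.00794, gave 0 lists past the threshold; over 32 lists that p alone is adjusted to 0.254, and 6 lists would have to reach it together to pass, so this 0 says little. The smallest exact p was 0.0159, for epithelial-mesenchymal transition genes (adjusted 0.339), with 0.0238 for red blood cells and 0.0317 for the stress list. The first of these scores counts the rise of Cdh1, a gene that the transition lowers. Of 467 list members measured, 47 had an unadjusted p under 0.05 by limma and 0 passed over all genes. The first principal component held 25.4% of the variance and did not part the groups (exact permutation p = 0.349).

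**Figure D3:**
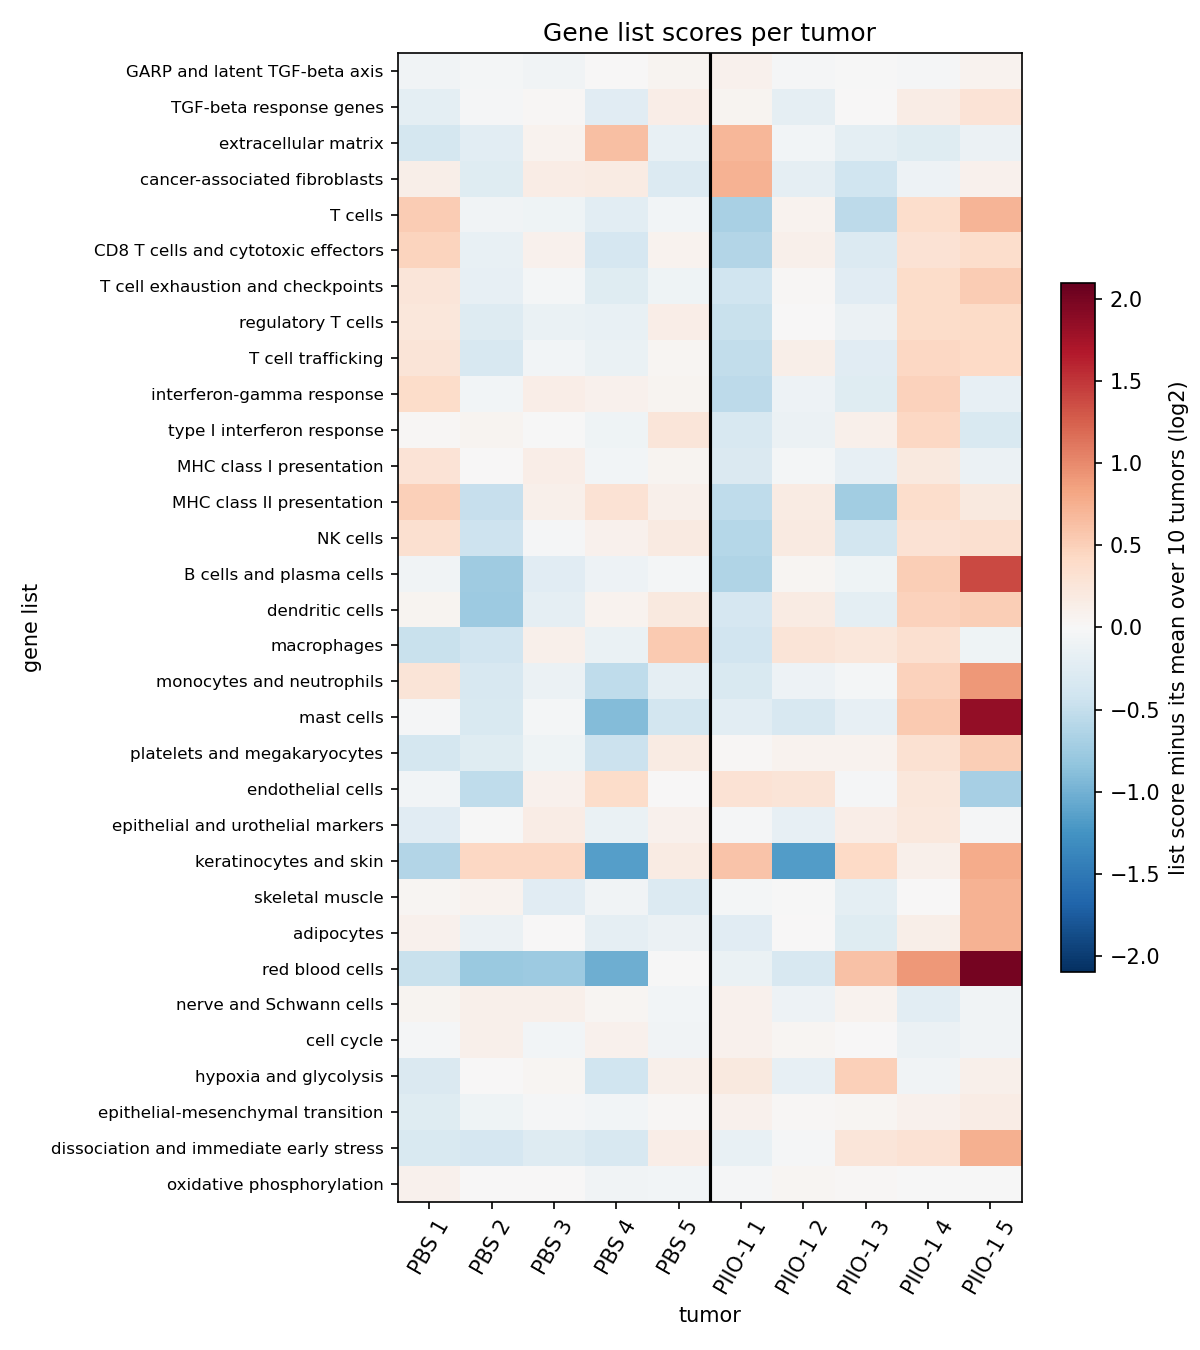
Scores of 32 gene lists (mean log2(normalized count + 1), minus the mean over the 10 tumors) in each of 5 PBS and 5 PIIO-1 tumors, one column per tumor. T cell lists are high in PBS tumor 1 and in PIIO-1 tumors 4 and 5 and low in PIIO-1 tumor 1, and red blood cell and mast cell scores are highest in PIIO-1 tumor 5.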

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

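The tests of tumor 5, blood, handling and leukocyte content, of the type I interferon list against Ifi208 and of regroupings for the limma count were chosen after the results they measure, or parts of them, had been seen; the other tests were set before, but how the values of the haplotype, handling and leukocyte tests were read was revised after they had been seen.

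A tumor stood far from the other 4 of its group (gap to its neighbour over the group's range above 0.71) in 15 of 248 groups checked, where chance gives about 1 in 20, or 12.4. PIIO-1 tumor 5 was the highest of its group for skeletal muscle genes (ratio 0.772), Cma1 (0.762), Ppbp (0.777), whole reads (0.734) and the share of mitochondrial reads (0.770). PBS tumor 5 was the highest of its group for the stress list (0.855), Hbb-bs (0.762) and the globin share (0.770) and the lowest for Def8 (0.811). PBS tumor 1 was the highest for T cell genes (0.779) and Tapbp (0.745), and PBS tumor 2 the lowest for B cell genes (0.738) and Klra1 (0.909). PIIO-1 tumor 1 was the highest for extracellular matrix genes (0.794) and PIIO-1 tumor 3 the lowest for H2-Oa (0.794).

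Regroupings of the 10 tumors do not exclude chance for the counts by camera and DESeq2. For limma they decide nothing, because it called 0 genes in the real grouping (at most 1 in the others), which all 100 of 100 groupings reach whatever the data. Camera with a preset correlation called 13 lists in the real grouping, and 42 of 100 groupings gave at least as many (highest other 19, median of the others 11). DESeq2 called 3 genes in the real grouping, and 14 of 40 groupings gave at least as many; the highest other grouping gave 551 genes. A count so far above the real one may reflect a structure among the samples, which was not tested.

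Ifi208 was lower in all 5 PIIO-1 tumors than in any PBS tumor. A lower type I interferon response as its source is argued against by the list of that response, whose median difference was -0.076, against -1.30 for Ifi208. For a haplotype of the Ifi200 cluster that differs between the mice, 0 of the 16 other genes measured within 1 Mb separated the groups. This cannot exclude a haplotype, which need not move its neighbours enough to part all 5 tumors of each group. Of the 16 genes, 12 are Ifi200 family genes whose reads are uncertain where copies are near-identical. A variant acting on Ifi208 alone was not tested. Reads exchanged with the 12 other Ifi200 family genes cannot be told apart from a change of Ifi208, because their summed counts differed by -17.0 with an SE of 3687, far above the 311 normalized counts that Ifi208 differed by. An effect of the antibody on Ifi208 stays open as a hypothesis beside chance, a haplotype and an exchange of reads.

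Red blood cell and stress genes had mean differences of 1.22 (SE 0.45) and 0.46 (SE 0.18) between PIIO-1 and PBS tumors, called by camera with a preset correlation but not with an estimated one (adjusted p = 0.488 for both) or by fry (adjusted p = 0.366 for both), and 0 members passed over all genes. Without PIIO-1 tumor 5 they were 0.87 (SE 0.34, exact permutation p = 0.0397) and 0.33 (SE 0.14, exact permutation p = 0.0714), above 0.61 and 0.23, the level at which 1 library would carry the difference, but by less than an SE. More blood left in the tumors would tie platelet genes (Ppbp, Gp1ba and Itga2b) to red blood cell genes, and within groups their scores had r = 0.618 (Spearman's rho 0.418, permutation p = 0.0964 for r, 10 tumors) but r = -0.107 without the 2 tumors farthest from the median, so the relation rests on those. Longer handling or dissociation may raise heat shock genes with immediate early genes, and the 5 heat shock genes had a mean of 0.55 (SE 0.25, exact permutation p = 0.0794) and the 13 others 0.42 (SE 0.18, exact permutation p = 0.0476). Neither chance, 1 library, blood, handling nor the antibody itself can be excluded for these genes. Regroupings of the 10 tumors did not exclude chance for the count of lists called, and the labels give no order or duration of collection.

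Interferon-gamma response genes had a mean difference of -0.24 (SE 0.18) between PIIO-1 and PBS tumors, called by camera with a preset correlation but not with an estimated one (adjusted p = 0.713), and 0 members passed over all genes. A lower leukocyte content could give this, but Ptprc, the leukocyte gene CD45, differed by 0.11 (SE 0.21) in the other direction. With the level of Ptprc as a covariate the mean difference of the list was -0.30 (SE 0.12), farther from 0 than without it, by more than 2 SE from 0 and still called by camera with a preset correlation (adjusted p = 7.30e-11); an estimated correlation was not run with the covariate. Because Ptprc was higher in PIIO-1 tumors, a list that rises with it had to move farther from 0 with this covariate. That move adds nothing beyond the difference of Ptprc itself, a single gene that lay within its SE of 0. A lower content of leukocytes as a whole is therefore not decided by this test, and a shift among leukocyte types was not tested. The difference depends on single tumors, at -0.13 without PIIO-1 tumor 1 and -0.39 without PIIO-1 tumor 4, and an effect of the antibody stays an untested hypothesis beside chance.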

How the results depend on the processing

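Leaving out PIIO-1 tumor 5 and PBS tumor 4 together, the Ptprc covariate, and DESeq2 with each tumor left out were chosen after the data were seen, as was DESeq2 on the kept genes after a first fit without a filter. limma called 0 genes under every alternative run with it, including each tumor left out, and edgeR 0, while DESeq2 called 3, DESeq2 on all genes with a read called 2, and DESeq2 called 4, 2, 1, 8 and 39 without PBS tumors 1 to 5 and 29, 13, 2, 38 and 1 without PIIO-1 tumors 1 to 5. Over all fits with 1 tumor left out the count ran from 0 to 39. Camera's 13 lists became 0 with an estimated correlation and 0 with fry, and the number of lists ran from 10 to 15 with 1 tumor left out; array weights gave 10 (without MHC class II, mast cells and epithelial-mesenchymal transition), a minimum mean of 50 gave 11 (without B cells, and with too few platelet genes left to test), and no filter 12 (without platelets); the added alternatives gave 12 without both tumors and 17 with Ptprc. The count of list scores past the threshold was 0 under the alternatives run for it (not the trend, array weights or Ptprc), with 0 at both ends when 1 tumor was left out; as a single list cannot pass, this says nothing about stability. The cause of the DESeq2 difference was not tested; the correlations estimated for the 13 called lists (0.0478 to 0.818) lie above the preset 0.01, which widens the spread camera allows, and fry compares a list with 0 and not with other genes.

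Tumors that share a number were not more alike than other pairs once the group means were taken out. Their correlations ran from -0.206 to 0.0954 (mean -0.0465), against -0.241 to 0.267 (mean 0.0118) for PBS and PIIO-1 tumors of different number. Only 1 of 5 PBS tumors correlated best with the PIIO-1 tumor of its own number. With 5 tumors per group this cannot exclude a pairing, which the labels do not state. With the replicate block, limma called 0 genes, camera 12 lists (the MHC class II call was lost, adjusted p = 0.0571) and the list scores 0, which a paired permutation of 5 pairs cannot exceed.

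For the 89 genes that the naming rule picks and the lists named, 0 values reversed past a threshold. For genes, 2000 values stayed on their side with their sign, 40 changed sign without passing and 2 passed only by DESeq2; for lists, 614 stayed, 38 changed sign without passing, 55 lost and 26 gained the call; for list scores, 552 stayed and 53 changed sign without passing. Depth limits mainly PBS tumor 4, in which 3 reads are worth 4.68 normalized counts.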

Other observations

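The relations across tumors and the genes in this part were chosen after the data were seen.

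T cell scores varied more between tumors of the same group than between the groups. They ran from 8.26 (PBS tumor 4) to 9.02 (PBS tumor 1) in PBS and from 7.80 (PIIO-1 tumor 1) to 9.20 (PIIO-1 tumor 5) in PIIO-1 tumors, on the mean log2(normalized count + 1) scale. Over the 10 tumors, 11 other list scores were set against the T cell score. The exhaustion and checkpoint score had r = 0.949 (permutation p = 4.0e-05, adjusted 0.000440; Spearman's rho 0.939, permutation p = 0.000200, adjusted 0.00115) and r = 0.895 without PIIO-1 tumors 1 and 5, which lie farthest from the median. The CD8 and cytotoxic score had r = 0.930 (permutation p = 0.00010, adjusted 0.000550; rho 0.939, permutation p = 0.000210, adjusted 0.00115) and r = 0.910 without those 2 tumors. The regulatory T cell score had r = 0.886 (permutation p = 0.000890, adjusted 0.00326; rho 0.867, permutation p = 0.00209, adjusted 0.00766) and r = 0.762 without them, and the MHC class II score r = 0.755 (permutation p = 0.0121, adjusted 0.0302; rho 0.733, permutation p = 0.0195, adjusted 0.0429) and r = 0.762. The B cell score had r = 0.726 (permutation p = 0.0137, adjusted 0.0302; rho 0.758, permutation p = 0.0151, adjusted 0.0416) but r = 0.379 without them, so that relation rests on those tumors. Centred on the group means, these 5 relations had r between 0.773 and 0.979. The other 6 lists (interferon-gamma response, MHC class I, TGF-beta response, extracellular matrix, cell cycle and oxidative phosphorylation) had r of 0.610, 0.605, 0.213, -0.584, -0.600 and 0.379 and did not pass (adjusted permutation p between 0.0896 and 0.547). Without PIIO-1 tumors 1 and 5 their r was 0.835, 0.899, -0.050, -0.411, -0.450 and 0.448, so the interferon-gamma and MHC class I relations were closer among the other 8 tumors; these values were not tested.

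Gapdh, a glycolysis enzyme often taken as a reference transcript, ran from 1608 normalized counts in PBS tumor 2 to 14156 in PIIO-1 tumor 3, and its difference between the groups had an SE of 0.63. The neighbouring enzymes of the pathway spread far less, with an SE of 0.10 for Aldoa, 0.13 for Pgk1 and 0.10 for Ldha. Gapdh and these enzymes are members of the hypoxia and glycolysis list, and how reads were assigned to Gapdh was not tested.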
